A study of Sus scrofa with 12 samples.

How the data were processed

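PARE libraries were made from total RNA of loin muscle of 12 female pigs slaughtered at 100 ± 2 kg and recorded at day 180, with RNA integrity numbers over 7, per the labels' protocols. CASAVA 1.8.2 and FastQC are named in the submitters' processing notes. The tables are PAREsnip output per the file headers. The aligner, genome build, annotation, small RNA input and the filter that chose the rows are not given in the sources used here. The series' design text speaks of chickens, while every sample is labelled pig, and the sample labels were followed.

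The deposited tables give, per the file headers, a category score from 0 to 4 (0 the strongest evidence), an alignment score and a fragment abundance. Fragment abundance has an unexplained excess of multiples of 20 (80.2% of values of 20 or more), so it was used as a score and not as reads. The deposited p-value of each interaction was rounded by the authors to 2 decimals and never exceeds 0.05. The deposited weighted and normalized abundances are signal values: the weighted value divides abundance by a whole number of matching positions, and the normalized value of the authors multiplies that by a factor whose scale is not given. In 5 tables the rows fall into 2 classes of factor, as if 2 runs had been joined. Factors under 0.15 were called deep and the others shallow. By that rule 5 libraries had shallow rows only and 2 had deep rows only.

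Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, with intervals from scipy 1.17.1 and plots from matplotlib 3.10.9. A target was any gene listed in a row, 1416 identifiers, of which 1330 had a symbol in the files or the reference table and 1198 matched that table. Nuclear positions are listed on both strands, and genes of either strand were kept. A total of 10 weighted values in Hampshire high MM replicate 2 look like spreadsheet dates, so the normalized values were used. A row without a category was kept, as were 4 rows without an end coordinate. The sum of listed start and cleavage position was constant over overlapping windows of the same cut (82.4% of windows shared it with another), and served to count interactions once. The size of each small RNA input was inferred from the ratio of the small RNA abundance columns. Unnamed small RNAs are numbered per library, so only named miRNAs were matched between libraries.

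Low and high MM were compared by exact permutation within breeds (216 relabellings, two-sided), and breeds over all 34650 partitions into 3 groups of 4. Target detection used presence or absence in a library with Benjamini-Hochberg adjustment at 0.05. Abundance was tested with limma 3.58.1 in R 4.3.3 on log2(normalized abundance + 1), taking the largest site per gene and library, with breed and MM as factors. Overlap was the Jaccard index of target sets. On simulated presence data for 307 targets, 100 of 100 completely split targets were recovered in the MM comparison and 0 of 30, since 57 are needed by arithmetic. Replicate numbers come from the labels, which tie no number to a shared litter, batch or day. Animals are separate samples per the labels. Genes were named by a rule fixed before the data were examined: the 15 targets in the most libraries, the 10 with the largest surplus in either MM group by the titles (ties by the same sign in more breeds, then abundance, then alphabet), up to 5 per breed in its 4 libraries and at most 2 others, the 4 leading members of each gene list, the 10 small RNAs with the most rows, with the members of the miRNA lists, and in the abundance fit the 5 with the smallest p. Alternatives fixed before the data were examined were the tab-name reading, leaving out Pietrain or each library, replicate blocks, stricter category and p-value, other units of counting, other pseudocounts and scaling. Settings with shallow rows only, with positions counted once, without miR-4331-5p and with a single normalization step were added after the data had been seen.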

Results

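Cleavage of messenger RNA was surveyed in the loin muscle of 12 female pigs by parallel analysis of RNA ends (PARE, or degradome sequencing), which captures the 5′ ends of cleaved transcripts. PAREsnip pairs such ends with small RNAs whose sequence would direct a cut there. The animals came from 3 breeds, Hampshire, Pietrain and Polish Large White, with 4 libraries each. In every breed 2 libraries were titled low MM and 2 high MM. MM is not spelled out in the labels, and the series title speaks of muscle mass. The titles and the tab names of the deposited workbook disagree for the 4 Pietrain libraries, so that high and low are exchanged there. The shear force in the labels, light or heavy, follows the titles in all 12 libraries, and whether it was recorded separately is not stated. Groups follow the titles below, and the tab-name reading is given beside many of the values. The tables hold 19855 rows, from 699 in Polish Large White high MM replicate 2 to 2949 in Pietrain low MM replicate 2. They list only retained interactions, so a target missing from a library is unlisted, not measured at 0. The read depth of the libraries is not given. The ratio of normalized to weighted abundance takes a value per table, or 2 in 5 of the tables. Its inverse, summed over both classes where a library had 2, serves here as relative depth. It was 2.40 to 2.95 in libraries with rows of the shallower class alone and 15.2 to 36.9 in the 7 libraries with rows of the deeper class. All 6 low-MM libraries held rows of the deeper class, against 1 of the 6 high-MM libraries, so depth and MM group were largely confounded.

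The first question was which target genes were listed in loin muscle whatever the animal. Targets listed in all 12 libraries were 3 genes, CA3 (ENSSSCG00000006141), TPM1 (ENSSSCG00000004570) and PPP1R2 (ENSSSCG00000039249). CA3 encodes the carbonic anhydrase abundant in muscle, TPM1 a tropomyosin of the thin filament, and PPP1R2 an inhibitory subunit of protein phosphatase 1. Their largest normalized abundances averaged 0.0799 ± 0.110 for CA3, 0.175 ± 0.472 for TPM1 and 0.0297 ± 0.0253 for PPP1R2 (SD, n = 12 libraries; the scale is not given). The TPM1 mean rested largely on Hampshire high MM replicate 2, with a mean of 0.0391 ± 0.0367 without it, and CA3 on Hampshire low MM replicate 2, with 0.0485 ± 0.0203 without it (SD, n = 11 each). All 710 rows of CA3, all 129 of PPP1R2 and 144 of the 175 of TPM1 name the gene on strand -1, although window positions run along strand 1. That these transcripts themselves were cut is therefore not established. Uniform random draws of each library's number of targets from the 1416 listed genes gave 0 such genes in 1000 simulations, a bound that draws of this size almost always give and that ignores transcript abundance. ND5, a subunit of respiratory complex I, was listed in 11 libraries. CYTB of complex III, COX3 of complex IV and FKBP5, a co-chaperone of steroid receptors, were each listed in 10. ATP2A1, the fast-fibre calcium pump, and ACTA1, skeletal actin, reached 9 libraries. DSP, COX1 and ENO3, the muscle enolase, reached 8, and MYLK2, C12orf45 and ACTG1 reached 7. At the other end, 1105 targets (78.0%) were listed in a single library. Of the 3 genes in all libraries, 1 remained in all when rows of miR-4331-5p were left out.

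**Figure D1:**
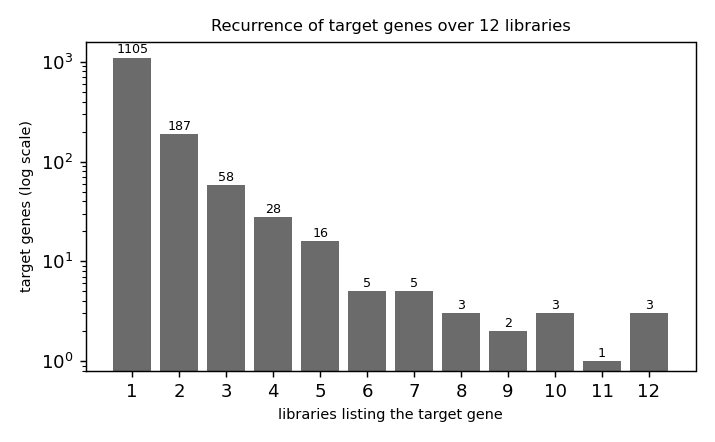
Number of target genes (vertical axis, log scale) by the number of libraries that list them (horizontal axis, 1 to 12). Most targets, 1105, are listed in 1 library and 3 are listed in 12.

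Of the 39 named interactions in at least 5 libraries, several belonged to miR-4331-5p. The position in PPP1R2 on chromosome 13 and that in TPM1 on chromosome 1 were assigned to miR-4331-5p in all 12 libraries. The sums of listed start and cleavage position were 132460444 and 108993852. The genome build is not given in the sources used here. In CA3 on chromosome 4, miR-499-5p, a muscle miRNA encoded in a myosin gene, was paired with position 51227874 in 11 libraries, and miR-378 with position 51227536 in 10. On the mitochondrial genome, miR-206, a muscle-specific miRNA, was paired with CYTB at position 16421 in 10 libraries. The let-7 members let-7a, let-7e, let-7f-5p and let-7i-5p, and miR-98, shared position 14460 in ND5 in 9 libraries. miR-129a-5p was paired with ACTA1 in 9 libraries and miR-143-3p with COX1 in 7. miR-133a-3p was paired with COX3 at position 10260 in 7 libraries and at the neighbouring 10259 in 5. It was the only small RNA listed for COX3, which was listed in 10 libraries. By rows, miR-4331-5p led with 2576 (23.9% of interactions when each position was counted once), followed by miR-499-5p with 990, miR-133a-3p with 952, miR-98 with 722 and let-7a with 703. Next came let-7i-5p with 685 rows, the unnamed pair NA71/NA72 with 536, miR-378 with 524, the unnamed NA24 with 506 and miR-155-5p with 487. Nuclear windows are listed once per strand and mitochondrial windows apparently only once. The ACTA1 position held 312 rows while 157 rows named ACTA1, against 227 and 228 for COX1. Rows therefore weigh nuclear positions more heavily, and an order by windows would differ. Numbers of unnamed RNAs are specific to a library, so NA24 need not be the same RNA in its 2 libraries. The fragments matched by miR-4331-5p had a median of 326 matching positions, and those at TPM1 and PPP1R2 medians of 1694 and 1747. Its positions in FKBP5, ATP2A1 and DSP had medians of 1275, 1700 and 1704, so the place of those fragments in the genome is uncertain. In 11 of the 12 libraries TPM1 and PPP1R2 had the same largest fragment abundance, so the recurrence of these 2 genes cannot be counted as independent and their place in the genome is uncertain.

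Low-MM libraries were compared with high-MM libraries in how much cleavage was listed. High-MM libraries held 1334 ± 644 rows and low-MM libraries 1975 ± 846 (SD, n = 6 each). The difference of -640.8 was smaller than the spread between libraries (two-sided exact permutation test within breeds, p = 0.194, 216 relabellings). With the Pietrain groups as in the tab names it was -376.5 (exact permutation p = 0.435). Division by relative depth turned the direction (324.2, exact permutation p = 0.0278), but the divisor nearly separates the MM groups and so sets that direction by itself. Among rows of the shallower class alone it was 20.3 (exact permutation p = 0.926, 10 libraries). Many rows were overlapping windows of the same cut. Counted once per small RNA and position, high-MM libraries held 230 ± 159 interactions and low-MM libraries 260 ± 106 (SD, n = 6 each; exact permutation p = 0.750), and by the tab names the difference was 18.8 in the other direction. Between breeds, Hampshire held 2023 ± 752 rows, Pietrain 1683 ± 910 and Polish Large White 1258 ± 713 (SD, n = 4 each; exact permutation test of the between-breed variance, p = 0.414).

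**Figure D2:**
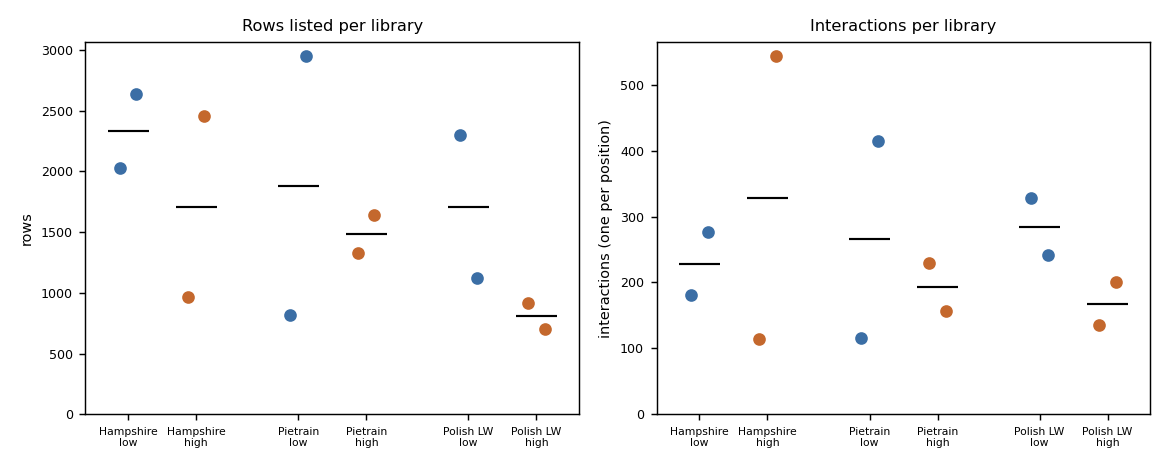
Rows listed per library (left, number of rows) and interactions counted once per small RNA and position (right), by breed and by MM group from the titles. Points are libraries (blue low MM, orange high MM) and lines are means of 2. The highest interaction count, 543, is Hampshire high MM replicate 2.

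Categories 0 and 1 mark the strongest degradome evidence, a peak at the maximum of the searched sequence. Cleavage positions ran from 10 to 71 in overlapping windows, so the peak need not be the maximum of the whole transcript. Their share was 8.41% ± 7.13 of rows in high-MM and 10.2% ± 2.49 in low-MM libraries (SD, n = 6 each; two-sided exact permutation test within breeds, p = 0.620). It ran from 2.29% (95% Wilson interval 1.41 to 3.69) in Polish Large White high MM replicate 2 to 20.6% (18.1 to 23.3) in Hampshire high MM replicate 1. The intervals cover counting error only, and rows of the same cut are not independent. The share was 11.1% ± 6.42 in Hampshire, 8.56% ± 4.07 in Pietrain and 8.17% ± 5.79 in Polish Large White (SD, n = 4 each; exact permutation p = 0.734). Leaving out Hampshire high MM replicate 2 or keeping categories 0 to 2 turned the sign of the MM difference.

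The next comparison asked which target genes were listed more often at high or low MM. None of 307 genes seen in 2 to 10 libraries differed after Benjamini-Hochberg adjustment of exact permutation tests, and 0 had an unadjusted p under 0.05. The genes with the largest surplus in low-MM libraries were SSU72 and COL3A1, each in 4 low-MM and 0 high-MM libraries. COL3A1 encodes the fibrillar collagen III chain, and its exact permutation p was 0.0556 (adjusted p = 1). BDH1, PFKFB1, TPM2, CRYAB and HSPB2 were each listed in 3 low-MM and 0 high-MM libraries. TPM2 encodes a tropomyosin, and CRYAB and HSPB2 encode small heat shock proteins. CRYAB and HSPB2 had the same listings, 64 rows each, all with miR-125a. ATP2A1 was listed in 6 low-MM and 3 high-MM libraries, and GNB1 and BCAT2 in 4 and 1 each. In the other direction, B2M, the light chain of MHC class I, was listed in 3 high-MM libraries and 1 low-MM library, and CYTB in 6 and 4. RABGAP1L, GDI2, SMU1, KTN1, NAA15, PSMD1, TMEM245 and HABP4 were each listed in 2 high-MM and 0 low-MM libraries. Most of these surpluses depended on the reading of the Pietrain groups. By the tab names COL3A1 and B2M stood at 2 and 2, CYTB at 5 and 5, and the 8 genes from RABGAP1L to HABP4 at 1 and 1. SSU72 stood at 3 low-MM libraries and 1 high-MM library, BDH1, PFKFB1, TPM2, CRYAB and HSPB2 at 2 and 1, ATP2A1 at 5 and 4, GNB1 at 3 and 2, while BCAT2 stayed at 4 and 1. COX7A1, a subunit of complex IV, stood at 5 low-MM and 2 high-MM libraries by both readings, and MYLK2 and C12orf45 at 5 and 2 by the titles and 6 and 1 by the tab names. In shallower rows alone, low and high MM stood at 1 and 2 for COX7A1, 2 and 3 for ATP2A1, 0 and 1 for GNB1, 1 and 1 for BCAT2, 2 and 1 for MYLK2, and 2 and 2 for C12orf45, over 4 low-MM and 6 high-MM libraries. By the same count COL3A1, PFKFB1, TPM2, CRYAB and HSPB2 stood at 2 and 0, SSU72 at 1 and 0, and BDH1 at 0 and 0. B2M stood at 0 and 3, CYTB at 4 and 6, and SMU1 at 0 and 1. RABGAP1L, GDI2, KTN1, NAA15, PSMD1, TMEM245 and HABP4 stood at 0 and 2. The design allows no exact permutation p below 0.00926, so at least 57 targets would have to be split completely for any to pass.

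Between breeds, 0 of the 307 genes differed after adjustment and 2 had an unadjusted p under 0.05. PTP4A2, a protein tyrosine phosphatase, was listed in 4 of 4 Pietrain libraries and in none of the other 8 (exact permutation p = 0.00606, adjusted p = 1). The 6 rows of PTP4A2 came from 2 interactions, with miR-4331-5p and miR-376c-3p, so no single cut need recur in all 4. TFCP2, a transcription factor, was listed in 4 of 4 Hampshire libraries, 2 Pietrain libraries and no Polish Large White library (exact permutation p = 0.0390, adjusted p = 1). Its miR-4331-5p position was listed in 3 Hampshire and 2 Pietrain libraries. That position had a median of 1815 matching positions, so its place in the genome is uncertain. No gene with a symbol was listed in all 4 Polish Large White libraries and at most 2 others. At least 38 genes as specific as PTP4A2 would be needed for a call.

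Abundance could be compared for the 3 genes listed in all libraries. The difference between high and low MM on the log2(value + 1) scale was 0.22 ± 0.22 (SE) for TPM1, -0.08 ± 0.07 for CA3 and 0.01 ± 0.02 for PPP1R2. The mean values of 0.175, 0.0799 and 0.0297 lie far below the added 1. The scale is therefore nearly linear, so these are not log2 fold changes, and single high libraries weigh heavily. Without the library of highest abundance (Hampshire high MM replicate 2, Hampshire low MM replicate 2 and Pietrain high MM replicate 1 in turn) each difference was -0.01, and by the tab names PPP1R2 turned to -0.02. None passed limma's moderated test (adjusted p = 0.527, 0.527 and 0.831; 0 with an unadjusted p under 0.05), nor did breeds differ in limma (adjusted p = 0.604 for each). When genes missing from up to 3 libraries were admitted, none passed either, and ND5 came closest at -0.05 ± 0.02 (SE; limma adjusted p = 0.206). Raw fragment abundance, neither divided by matching positions nor scaled, differed by -3.03, -2.40 and -2.58 on the log2 scale for TPM1, CA3 and PPP1R2 (limma adjusted p = 0.000117, 0.000570 and 0.000387). The 3 genes had the same SE there (0.604), so limma pooled their variance fully. TPM1 and PPP1R2 also had the same low-MM mean and SD (9.52 and 1.16). These p-values treat shared values as independent and are likely too small. With the scaling factor only, the differences were -0.35, -0.27 and -0.35 (limma adjusted p = 0.456 each). TPM1 and PPP1R2 had identical group means and SDs in that fit, so they are not separate measurements. With the division only, they were -0.15, -1.03 and -0.43 (limma adjusted p = 0.718, 0.0533 and 0.0874). Group means of divided values ran from 0.189 to 1.30 on this scale, where the added 1 compresses ratios. The loss of the call under division therefore does not show that matching positions carried the raw difference. The scaling factor nearly separates the MM groups, so its effect cannot be told apart from an MM difference.

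Libraries were compared in how many targets they shared. Pairs of the same breed and MM group had a mean Jaccard index of 0.0687 ± 0.0334 (SD, 6 pairs), and pairs of the same breed and different MM group 0.0686 ± 0.0250 (12 pairs; two-sided exact permutation p = 1). Pairs within a breed had 0.0686 ± 0.0271 (18 pairs) and pairs of different breeds 0.0668 ± 0.0216 (48 pairs; one-sided exact permutation p = 0.302).

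Target genes were then grouped by 19 lists fixed before the data were examined. Fast-fibre contractile genes made up 2.23% ± 0.836 of the targets of a high-MM library and 2.54% ± 0.702 of a low-MM library (SD, n = 6 each). TPM1, ATP2A1, MYLK2 and MYH2 led them, the last in 5 libraries. Common sarcomere and Z-disc genes stood at 1.99% ± 1.03 and 2.29% ± 1.38, led by ACTA1, DES in 6 libraries, NEB in 5 and MYOM2 in 4. Mitochondrially encoded genes stood at 2.47% ± 0.471 and 1.98% ± 0.662, led by ND5, CYTB, COX3 and COX1. Glycolysis and glycogen genes stood at 1.77% ± 1.00 and 1.95% ± 1.02, led by ENO3, GPI in 5 libraries, PYGM in 4 and PFKFB1 in 3. By the tab names high minus low was 0.0202 percentage points for mitochondrially encoded and 0.184 for glycolysis and glycogen genes, and in shallower rows -2.30 and -1.66, so neither direction held (exact permutation p = 0.0185 for the last, adjusted p = 0.352). Oxidative metabolism genes were led by COX7A1 in 7 libraries and UQCRC2 in 5, and calcium handling genes included PPP3CB in 4. Slow-fibre genes were few, with ATP2A2 and CSRP3 in 2 libraries each. Of the myogenic regulators HDAC5 was listed in 2 libraries, TEAD1 and MEF2B in 1, and of muscle growth signalling INSR, FSTL1, MTOR and RPS6KB1 in 1 each. Protein breakdown was represented by PSMD1, PSMD2, FBXO40 and CAPN3 in 2 libraries each, and translation by EEF2, EIF4G2 and EEF1D in 2. Extracellular matrix was led by COL3A1 and LAMA2, and stress genes by HSPB2. Members of the lists for other cell types were rare, with B2M in 4 libraries, LPL in 2, and CD14, SLA-2, ALAS2 and VIM in 1 each. Not all of these genes are specific to the cell type of their list. No endothelial or Schwann cell marker was listed. The share of 0 lists differed between MM groups (exact permutation tests, Benjamini-Hochberg over the lists, smallest adjusted p = 1), and 0 had an unadjusted p under 0.05. No member of any list differed, adjusted over the list alone or over all genes tested. Between breeds 1 list, glycolysis and glycogen, had an unadjusted exact permutation p under 0.05 (p = 0.0144, adjusted p = 0.273).

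Small RNAs were grouped likewise into 8 lists. Unless stated, shares are of rows, in which nuclear windows count once per strand. The let-7 family took 18.6% ± 1.79 of rows in low-MM and 9.59% ± 10.4 in high-MM libraries (SD, n = 6 each; two-sided exact permutation p = 0.0556, adjusted p = 0.444). By the tab names the difference was -11.6 percentage points (exact permutation p = 0.00926, the smallest possible, adjusted p = 0.0741). The ND5 position alone held 2882 rows of 7 small RNAs in 9 libraries. The muscle miRNA families took 12.9% ± 4.48 and 15.6% ± 7.29 in low and high MM, but the difference was -1.42 by the tab names and -1.41 in shallower rows. Vascular and fibroblast miRNAs kept no direction: high minus low was 1.93 percentage points of rows, resting on 15.4% in Hampshire high MM replicate 1. With positions counted once they took 5.57% ± 12.4 in low and 0.709% ± 0.546 in high MM (SD, n = 6 each, exact permutation p = 0.741). Erythroid and immune miRNAs differed by -0.404, which turned to 0.715 by the tab names. The miR-23/27/24 clusters took 2.05% ± 1.45 and 0.949% ± 1.88, the miR-30 family 1.24% ± 1.54 and 0.827% ± 1.76, and the miR-17/92 clusters 1.15% ± 0.771 and 0.699% ± 1.32. These high-MM means rested largely on Pietrain high MM replicate 2, at 4.76%, 4.39% and 3.29%, the only high-MM library with deep rows. By the tab names the miR-17/92 difference was -1.51 (exact permutation p = 0.0185, adjusted p = 0.0741), and in shallower rows 0.0254 (exact permutation p = 1). The miR-26 and miR-29 families stayed under 0.05% on average in both. Of the lists, 0 differed after adjustment by the titles or by the tab names. At an unadjusted exact permutation p under 0.05 there were 0 by the titles and 2 by the tab names. With a smallest possible p of 0.00926, a single list of the 8, or of the 19 gene lists, could not pass adjustment.

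**Figure D3:**
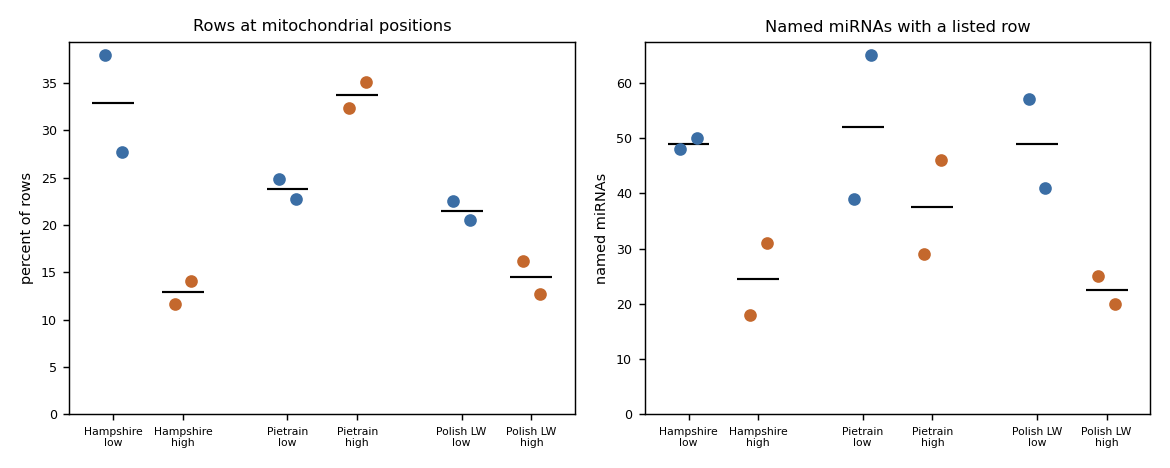
Share of rows at mitochondrial positions (left, percent) and named miRNAs with at least 1 listed row (right, number) per library, by breed and by MM group from the titles. Points are libraries (blue low MM, orange high MM) and lines are means of 2. The Pietrain high-MM libraries, 32.3% and 35.1%, lie above the Pietrain low-MM libraries, while in the other breeds high MM lies below low MM.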

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

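The test of run depth for the mitochondrial share was set down before its result was seen; those of the ND5 position, of exchanged Pietrain groups, and of depth and list length for named miRNAs were chosen after the result, or the counts behind it, had been seen.

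The share of rows at mitochondrial positions stood out because Pietrain went against both other breeds by the titles. Nuclear windows are listed on both strands, so this share of rows lies below the share of windows. High minus low was 9.98 percentage points in Pietrain, -7.06 in Polish Large White and -20.0 in Hampshire; the difference between breeds was not tested. With positions counted once, high minus low was -1.11 by the titles and -2.09 by the tab names (exact permutation p = 0.296 and 0.0278, adjusted 0.583 and 0.194), and the Pietrain groups overlapped. Over all breeds the difference by the titles was -5.69 (exact permutation p = 0.25, adjusted 0.583). By the tab names the sign is the same in all 3 breeds, and the difference of -12.3 had the smallest p the exact permutation allows (0.00926, adjusted over 14 measures 0.130). Depth of the runs is argued against, since in shallow rows alone the difference was -20.3 ± 2.17 (SE, exact permutation p = 0.0185). By breed it was -36.2 in Hampshire, -15.2 in Polish Large White and -9.41 in Pietrain. Polish Large White low MM replicate 2 and Pietrain low MM replicate 1 had no shallow rows. In Hampshire and Polish Large White, low-MM shallow rows came from libraries with both classes and high-MM rows from libraries without deep rows. Other differences between runs therefore stay confounded with MM. Without the ND5 position paired with let-7 members the difference by the tab names was -1.76 ± 2.01 (SE), but this mean hides opposite changes: -10.2 in Hampshire, -6.49 in Pietrain and 11.4 in Polish Large White, so the share of that position in the pattern stays open. Whether the Pietrain groups were exchanged in the titles or the tab names, or Pietrain pigs differ, cannot be told apart from the value of 9.98, since both give that sign; the shear force in the labels goes with the titles.

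Named miRNAs with a listed row numbered 28.2 ± 10.1 in high-MM and 50.0 ± 9.80 in low-MM libraries (SD, n = 6 each; exact permutation p = 0.0185, adjusted over 14 measures 0.194), and by the tab names the difference was -12.2 (exact permutation p = 0.194). In shallow rows alone the difference of -21.8 shrank to -7.17 ± 3.64 (SE; exact permutation p = 0.111) but unevenly, to 0.5 of -24.5 in Hampshire, -11.5 of -26.5 in Polish Large White and -10.5 of -14.5 in Pietrain, so the part of run depth stays open. In the 5 libraries with both classes of rows, the deep rows held more named miRNAs in 5. Length of the small RNA list, inferred from its abundance columns, stays open: the difference was 41.7 ± 37.1 entries (SE), and 5.5 ± 9.50 without the longest list. A difference between MM groups stays open and untested apart from depth.

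Of 65 groups checked, 4 had a library far from the rest, and chance flags about 1 in 20. Hampshire high MM replicate 2 held 543 interactions against 114 to 229 in the other high-MM libraries. Pietrain low MM replicate 2 had 2.89% of interactions on the mitochondrial genome against 5.77% to 6.11% in the other Pietrain libraries. The small RNA list of Polish Large White high MM replicate 1 held 424 entries, far above the other Polish Large White and the other high-MM libraries. Positions with no listed gene, which no gene comparison used, held 27.6% of interactions (810 of 2935).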

How the results depend on the processing

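The settings with shallow rows only, with positions counted once, without miR-4331-5p and with a single normalization step were chosen after seeing the data. The 0 calls for target detection by MM or breed, gene lists, miRNA families and abundance between breeds stayed 0 in the alternatives. For detection and lists by MM the smallest possible p was 0.00926, 0.0556 without Pietrain and 0.0312 with the replicate block, so 0 was nearly forced there. For the row difference between MM groups (-640.8), keeping categories 0 to 2 gave -612.7 (exact permutation p = 0.0278), and leaving out each library gave -996.7 to -285, the former past the threshold without Pietrain low MM replicate 1 (exact permutation p = 0.0370). The sign reversed per unit of relative depth (324.2, set by a divisor confounded with MM), in shallow rows (20.3, or 277.3 by the tab names) and in shallow rows with positions counted once (79.0). The share in categories 0 and 1 reversed with categories 0 to 2 (4.78), in shallow rows (1.44, or 1.22 by the tab names), and ranged from -4.11 to 0.577 when a library was left out. Overlap by MM reversed at p-values up to 0.01 (-0.000969) and in shallow rows (-4.27e-05 by either reading), and ranged from -0.0117 to 0.0105 without a library. Overlap by breed reversed without miR-4331-5p (-0.0020) and ranged from -0.00243 to 0.0063. Targets in all libraries numbered 0 with categories 0 to 2, which also left no abundance fit, 1 without miR-4331-5p, and 3 to 4 without a library. Raw fragment abundance gave 3 calls between MM groups against 0. TPM1 and PPP1R2 shared most of their raw values, so the 3 calls are not independent. Scaling alone or division by matching positions alone gave 0 again (1 and 0 unadjusted for division and scaling), with ratios compressed by the added 1 under division. Same-numbered replicates did not pair (correlations of deviations -0.0222, -0.0784 and 0.0663), and the replicate block (64 relabellings) gave -640.8 rows at p = 0.125. In all 4 tests of 0 calls (detection and abundance by MM and breed; those of detection chosen after the result was seen), 100 of 100 splits gave as many, with 0 the highest of the others, which a real count of 0 fixes beforehand, so the splits decide nothing.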

Other observations

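The strongest evidence recurred at few cuts, chosen here after their values were seen. Category 0 was reached in at least 3 libraries at 4 positions. The counts below are of positions, whether or not each row names the gene. let-7f-5p was paired with a position on chromosome 15 in 6 libraries, all in category 0, with a normalized abundance of 0.137 ± 0.0739 (SD, n = 6). The gene named there is CCNYL1, a cyclin Y-like gene. miR-23a was paired with ADAM19, a membrane metalloprotease, on chromosome 16 in 5 libraries, 4 of them in category 0, at 0.551 ± 0.367 (SD, n = 5) and with a median of 2 matching positions. miR-542-3p was paired with ACTG1, cytoplasmic actin, on chromosome 12 in 7 libraries and category 0 in 3. miR-6782-3p was paired with PFKFB1, an enzyme that sets fructose 2,6-bisphosphate levels, on chromosome X in 3 libraries, all in category 0, and low MM in 3 by the titles and 2 by the tab names; the gene there is on strand -1. TSPAN10 lies on the other strand at the ACTG1 position.

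The gene named for a cut lay on either strand about equally. Of 1542 nuclear interactions with a gene on a single strand, 53.3% had it on strand 1 (95% Wilson interval 50.8 to 55.8). All nuclear rows (100%) are listed on both strands, so the listing itself did not choose a strand. The share is no separate test of that. It shows only that genes on strand 1, along which the windows run, were little favoured. That windows of genes on strand -1 were read in the gene's direction is argued against: 67.4% of them shared start plus cleavage position with another window, and 0 percent shared start minus cleavage position. All 710 CA3 rows, all 129 PPP1R2 rows and all 192 ENO3 rows were on strand -1. So were 144 of 175 TPM1 rows, 35 of 38 FKBP5 rows and 222 of 225 COX7A1 rows. All rows of ATP2A1, ACTA1, MYLK2, ACTG1, DES, NEB, ADAM19 and CCNYL1 were on strand 1. Both tests were chosen after the result was seen, no biological explanation was tested, and transcription from the strand opposite CA3 stays open.

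In the 5 libraries with 2 classes of rows, interactions of named miRNAs in deep and shallow rows of the same library had a mean Jaccard index of 0.244, against 0.0733 over 65 deep and shallow pairs of different libraries. Of 191 cases in which a recurrent named interaction was unlisted in a library, 94 fell in libraries where that miRNA had no row at all. Neighbouring positions of the same miRNA, such as 10259 and 10260 in COX3, were counted apart, which adds to the unlisted cases. miR-4331-5p had rows in all 12 libraries, so its unlisted cases could not be among the 94.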
